A study of Mus musculus with 6 samples.

How the data were processed

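RNA was measured in 6 libraries of mouse GV oocytes, 3 WT and 3 labelled KO, each from 5 pooled oocytes. Per the labels' protocols, cDNA was made by Smart-Seq2, which primes on poly(A) tails and amplifies full-length cDNA. Libraries were built with the Nextera XT kit, which keeps no strand and no molecular identifiers, and were sequenced as 75-base read pairs. Per the labels' protocols, oocytes were obtained by enzymatic digestion of ovaries, and the protocol also describes the collection of granulosa cells by digestion of secondary follicles. Per the submitters' processing notes, the tools cutadapt, FastQC, STAR, DESeq and DESeq2 and the builds GRCm38 and mm10 were used. Versions of these tools and the gene annotation are not given in the sources used here.

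The deposited table gives normalized read counts per gene and library, a signal in which each value is the number of reads divided by a size factor of the authors, per the file headers, which name DESeq2 and Partek. Each column is a whole multiple of the value of 1 read (0.899 to 1.11). Dividing by that step gave whole reads for 100% of the values above 0, within a tolerance of 0.1 reads. Totals of recovered reads were 6450191, 7624575 and 7992598 in WT replicates 1 to 3 and 6583404, 6626841 and 7615374 in KO replicates 1 to 3. The most abundant 10 genes took 6.5% to 7.1% of the reads. A count of 0 allows up to 3 reads, or 0.375 to 0.465 CPM (reads scaled to the library's total), and this limit covers counting error only, since amplified reads are not independent molecules.

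The table holds 25353 genes, 16754 of them protein coding, none at 0 in every library and 0 from the mitochondrial chromosome. Of 24 symbols that a spreadsheet had turned into dates, 23 were restored by their position. Symbols matched GENCODE release M21 for 95.6% of genes. Among matched genes the end in the table lay 1 base past that of GENCODE in 95.5%, so positions are printed as the start and the base before the deposited end, on GRCm38. The annotation used here may differ from that of the authors.

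Groups and replicate numbers were taken from the sample titles. The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test for them. Because the values were normalized, the test it named for that case was used. Genes with a value of at least 1 in 3 libraries (18762) were transformed to log2(value + 1) and compared between all 3 KO and all 3 WT libraries with limma-trend (limma 3.58.1 in R 4.3.3), with no covariate. P-values were adjusted by the Benjamini-Hochberg method and a threshold of 0.05 was used. All fold changes are on the log2(value + 1) scale, which understates the change of low genes. Adjusted p-values are those of limma unless another tool is named. The count test was added afterwards as an alternative: edgeR 4.0.16 on the recovered reads, with TMM scaling, tested 13078 genes and called 480 higher and 365 lower in KO. Of the 615 genes called by limma, 575 were also called by edgeR and 558 by DESeq2 1.42.0. The biological coefficient of variation in edgeR was 14%.

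Before the data were examined, 32 gene lists were fixed, for mitochondria, stress, cell death, metabolism, oocyte functions and other cell types. The list of mitochondrially encoded proteins had no gene in the table, and 31 were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists. No list had an adjusted p under the threshold with an estimated correlation, where the smallest was 0.62. A second set test, fry, asks whether a list's genes move in a direction on balance and does not compare them with other genes. Counts "adjusted over the list alone" used the limma p-values of the list's own members.

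The genes named in the text follow a rule fixed with the lists. Mfn1 and Mfn2 are always named. Then come the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap of the groups, leaving out model symbols and pseudogenes. From each list up to 4 members past the threshold are named by smallest p, or the 2 of smallest p where none passed. Further members named beside small counts, with those counts adjusted over the list alone among them, were chosen after their values were seen. The result of 1 gene that the rule names is not reported here, though counts of named genes include it. To find near-identical copies, 75-base windows of each gene's longest transcript, taken every 25 bases, were aligned to all GENCODE M21 transcripts with minimap2 2.31-r1302, and a window that matched another gene with at most 1 mismatch counted as shared. Overlapping and antisense genes cannot be told apart in these libraries.

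The fits were tested on simulated data drawn from the means and library sizes of these libraries, with 200 genes changed. The changed genes were picked among those with a mean of at least 20 reads, so the recovery of lower genes was not measured. For KO against WT, limma-trend over 19184 simulated genes recovered 40.3% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 97% of 66 changed 4-fold. Of the 159 genes it called, 9 were unchanged (5.66%). Simulated genes of a like mean level were given a like spread between libraries, and no library was made to deviate as a whole. The shares recovered and unchanged may therefore differ in the real libraries. Camera called a list of 60 genes with a log2 change of -0.25 and none of 20 unchanged lists. The simulated genes were drawn independently of each other, so this does not show how camera acts on lists of correlated genes.

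Alternatives planned before the data were examined were DESeq2, other size factors, other filters, the legacy quasi-likelihood method and limma-voom on the recovered reads, a pseudocount of 0.1, other thresholds, the replicate number as a block and leaving out each library. For the gene lists the planned comparison was of size-factor with TMM scaling, and because the deposited values already carry size factors, TMM scaling was the alternative. Added after the data were seen were edgeR on recovered reads with TMM, limma with TMM scaling, with a filter of 5 CPM or with a replicate block, leaving out a library while keeping the genes of the 6-library filter, and the removal of each library's trend on GC content and transcript length. That trend was fitted by splines to the deviations from each gene's mean, over the 96.7% of tested genes with an annotated transcript. No pair of libraries differed by as little as sampling noise, with a chi-square per degree of freedom of at least 5.1.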

Results

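RNA was sequenced from mouse germinal vesicle (GV) oocytes, the fully grown female germ cells that are arrested at prophase of meiosis and hold a large store of maternal transcripts. The series asks what the loss of a mitofusin, an outer mitochondrial membrane GTPase that drives fusion of mitochondria, does to the oocyte transcriptome. There were 6 libraries, 3 from wild-type (WT) mice and 3 labelled knockout (KO), each made from 5 pooled oocytes of C57BL/6J mice stated to be 8 weeks old. The age field of the labels reads P1 instead, and the labels do not resolve this. Between 6450191 and 7992598 reads were assigned to genes per library, and between 19481 and 20102 genes had at least 1 read. All p-values measure the spread between these pooled samples, because nothing in the labels ties each pool to its own mouse.

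The labels disagree on the deleted gene. The title and the design text of the series name Mfn2, whereas the genotype and protocol fields of the samples name Mfn1. Mfn2 (chromosome 4, 147873599 to 147904704, minus strand, GRCm38) had normalized read counts of 25.5, 38.1 and 32.3 in the WT libraries and 5.25, 5.28 and 4.50 in the libraries labelled KO. It fell by 2.44 on the log2 scale (SE 0.38, limma adjusted p = 0.00487). The KO values rest on 5 reads in each library, and the gene-level counts do not say which exons those reads came from. Mfn1 (chromosome 3, 32529465 to 32579239, plus strand) stood at 340 ± 36.3 in WT and 386 ± 10.3 in KO (SD, n = 3 each). Its log2 fold change of 0.19 (SE 0.13) did not pass the limma test (adjusted p = 0.482). Every direction below is that of the libraries labelled KO against WT.

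**Figure D1:**
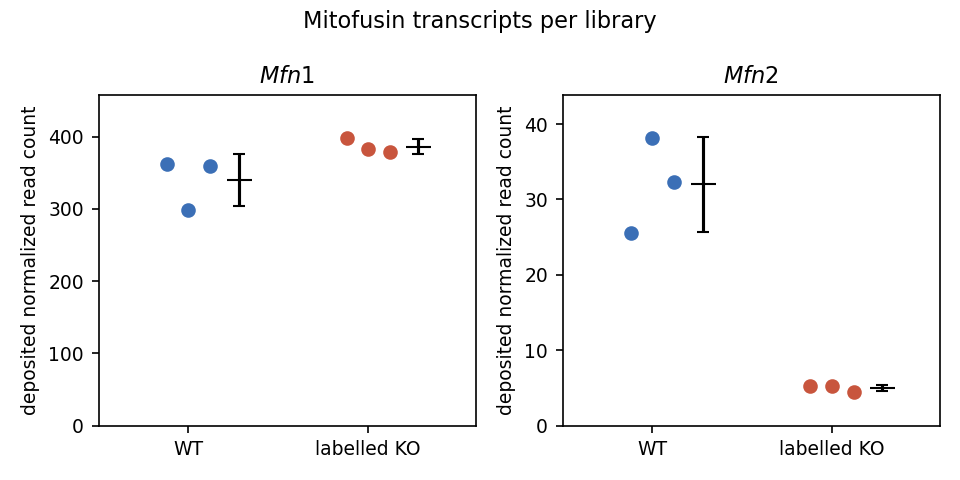
Deposited normalized read count (y axis, starting at 0) of Mfn1 and Mfn2 in each library, with points for libraries and bars for mean ± SD of 3 libraries. The KO points of Mfn2 sit between 4.50 and 5.28, below all WT points, while those of Mfn1 lie between 379 and 398.

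Under the naming rule, Mt1, Deup1 and Cdc5l were among the largest rises in the libraries labelled KO, and Cyp11a1 and Supt16 among the largest falls. Between the 2 groups, 351 genes rose and 264 fell in the libraries labelled KO, out of 18762 tested. The median size of these changes was 0.74 on the log2 scale, and 124 of the rises and 59 of the falls reached 2-fold. Protein-coding genes made up 305 of the rises and 209 of the falls. The CPM of the KO and WT libraries did not overlap in 607 of the 615 genes called, a separation that the test itself selects for. It did not overlap in 23.2% of all tested genes, where chance gives 10%. The first principal component held 42.8% of the variance and placed the 3 WT libraries between -19.9 and -14.4 and the 3 KO libraries between 13.9 and 19.4. KO replicate 1 stood apart on the second component, at -23.1 against 7.2 and 17.7 for the other KO libraries. Without KO replicate 1 the counts were 459 and 430, and without WT replicate 1, in which several markers of other ovarian cells were highest as given below, they were 172 and 90. They also moved by more than 1.5 times without WT replicate 2 (130 and 59), WT replicate 3 (71 and 41) or KO replicate 2 (181 and 140), and without KO replicate 3 there were 194 rises and 185 falls with the filter applied again to the 5 libraries, and 39 and 32 with the genes of the 6-library filter. With each library's trend on GC content and transcript length removed, 46.2% of the calls were rises, against 57.1% before.

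The largest rise under the naming rule was that of Mt1, a metallothionein that binds zinc and copper. Mt1 (chromosome 8, 94179082 to 94180327) went from 128 ± 160 in WT to 2328 ± 173 in KO (SD, n = 3 each). Its log2 fold change was 4.98 (SE 0.54, limma adjusted p = 0.000212), although edgeR on the recovered reads gave an adjusted p of 0.0833. WT replicate 1 had 313 normalized counts and the other WT libraries 27.9 and 43.4, and the log2 fold change was 6.02 without WT replicate 1 and 4.30 without WT replicate 2. Deup1, a component of the deuterosomes that multiply centrioles in ciliated cells (chromosome 9, 15559864 to 15627933), rose by 3.33 (SE 0.59), from 5.76 ± 6.4 to 53.4 ± 29.8 normalized counts (SD, n = 3 each). Its WT values rest on 3, 14 and 1 reads, and the log2 fold change was 4.09 without WT replicate 2 and 2.66 without WT replicate 3. The macrophage lectin gene Mgl2 rose by 3.23 (SE 0.52), from 3.15 to 38.9, and 20.6% of its 75-base windows also match other genes, Clec10a among them. Cdc5l, a core spliceosome component (chromosome 17, 45391892 to 45433707), rose by 3.22 (SE 0.30), from 25.5 to 232. It shares 53.8% of its windows with annotated copies such as Gm9029, so its counts are uncertain. Gli3, a transcription factor of the hedgehog pathway (chromosome 13, 15463235 to 15730026), rose by 2.33 (SE 0.31), from 28.6 ± 12.5 to 139 ± 29.0. It overlaps the antisense model Gm6556, and the library kit does not keep strand.

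Smaller among the 10 largest rises were Lias, which makes the lipoyl cofactor of mitochondrial dehydrogenases (log2 fold change 1.97), and C1d, a cofactor of the RNA exosome (1.96). The testis-enriched lactate dehydrogenase subunit Ldhc followed at 1.80, the zinc finger gene Zfp707 at 1.75 and Clp1, an RNA kinase of 3′ end processing, at 1.74. The adjusted p-values of these 5 in limma were 0.0265, 0.00487, 0.00443, 0.0148 and 0.0203 in that order. Zfp707 had an adjusted p of 0.14 in edgeR. Without WT replicate 3, Lias (adjusted p = 0.125), Clp1 (0.111) and Zfp707 (0.0791) no longer passed the limma test.

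The largest fall among the named genes was that of Cyp11a1, the side-chain cleavage enzyme that begins steroid synthesis in granulosa and theca cells (chromosome 9, 58006411 to 58027023). It had 604, 13.9 and 92.3 normalized counts in the WT libraries and 3.15, 5.28 and 4.50 in KO, and it fell by 4.17 (SE 0.83, limma adjusted p = 0.0135). The edgeR adjusted p was 0.25, and without WT replicate 1 the log2 fold change was -2.84 (limma adjusted p = 0.0341), without WT replicate 2 it was -5.51, and without WT replicate 3 -4.18 (0.0782). Aldh1a1, a retinaldehyde dehydrogenase, followed at -2.77 (SE 0.71, adjusted p = 0.043), with 79.8, 4.65 and 32.3 in WT and 2.11 to 3.15 in KO. Without WT replicate 1 its adjusted p was 0.182 and its log2 fold change -1.92, and without WT replicate 2 the fold change was -3.84. These 2 genes were highest in WT replicate 1, the library in which the medians of the granulosa, stromal and immune marker lists were highest, while those of the endothelial and surface epithelium lists were highest in WT replicate 3 and KO replicate 3.

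Other large falls had similar levels in the 3 WT libraries. Ier5l, an immediate early response gene (chromosome 2, 30471537 to 30474219), fell by 1.52 (SE 0.16, adjusted p = 0.000212), from 1213 ± 181 to 427 ± 115. Supt16, the large subunit of the FACT histone chaperone (chromosome 14, 52160414 to 52197416), fell by 1.35 (SE 0.15, adjusted p = 0.000212), from 768 ± 23.5 to 306 ± 64.2. Supt16 overlaps Rpgrip1 on the other strand, which holds 19.6% of its windows. Mid1, an X-linked microtubule-associated ubiquitin ligase, fell by 1.38 (SE 0.24), with 27.6% of its windows shared with copies such as Mid1-ps1. Xaf1, an interferon-inducible antagonist of the caspase inhibitor XIAP, fell by 1.92 (SE 0.41), from 68.0 to 20.6. Srcap, a chromatin remodelling ATPase, fell by 1.69, but 90.1% of its windows are shared with the overlapping models Gm42715 and Gm28198. The remaining falls of this size were Cfap57 (-1.56), a ciliary protein gene, the major histocompatibility gene H2-Aa (-1.42) and the carboxylesterase gene Ces1d (-1.42). Leaving out a single WT library ended the calls of Xaf1 (adjusted p = 0.0837 without WT replicate 3), Srcap (0.133 without WT replicate 2), Cfap57 (0.0905 without WT replicate 1), H2-Aa (0.0923 without WT replicate 2) and Ces1d (0.136 without WT replicate 1).

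**Figure D2:**
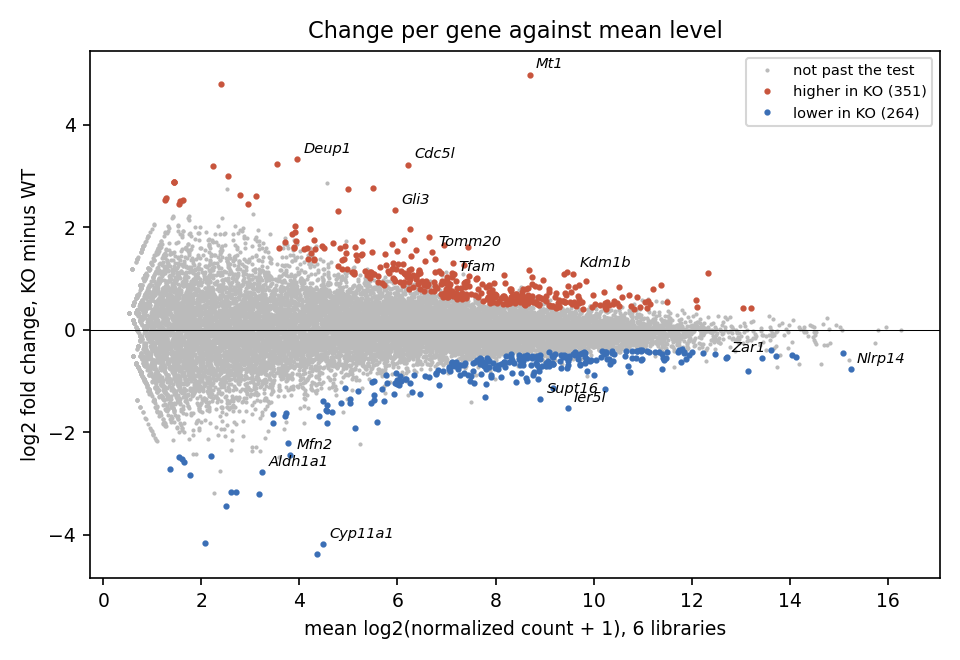
Log2 fold change of KO against WT (y axis) for the 18762 tested genes, against the mean of log2(normalized count + 1) over the 6 libraries (x axis). Red points are the 351 genes that rose and blue points the 264 that fell, and Mt1 lies highest among the labelled genes with 4.98 on the y axis.

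Of the 51 named genes that passed the test, 16 passed it in each of the 6 fits that left out 1 library and applied the filter again to the other 5. These were Mfn2, Mt1, Deup1, Mgl2, Cdc5l, Gli3, C1d, Ldhc, Ier5l, Mid1, Supt16, Tomm20, Kdm1b, Wee1, Ckap5 and Cenpe. The other 35 lost the call in at least 1 of these fits, without a change of sign: 23 without WT replicate 1, 26 without WT replicate 2, 32 without WT replicate 3, and 3, 21 and 18 without KO replicates 1, 2 and 3. With the genes of the 6-library filter kept instead, a form added after the data were seen, 32, 26 and 33 lost the call without WT replicates 1, 2 and 3, and 4, 21 and 40 without KO replicates 1, 2 and 3. In that form 8 passed in all 6 fits, namely Mfn2, Mt1, Cdc5l, Gli3, Ier5l, Supt16, Tomm20 and Kdm1b. Where a single library is named beside a gene, the filter was applied again, and for a lost call it is the one without which the adjusted p was highest. Of the named genes that passed, Lias, Cdc5l, Ppp1r15a, Cnot3, Cd9, Pde3a, Kdm1b, Bnc1, Rpl35, Mid1 and Srcap also overlap a gene on the other strand, whose reads cannot be told apart from theirs. Across all genes, 86 of the 615 kept their call in all 6 fits with the filter applied again, and 43 with the genes of the 6-library filter. Within 5 Mb of Mfn2, 5 of 148 tested genes were called (3.38%), against 609 of 18613 elsewhere (3.27%, two-sided Fisher's exact p = 0.817).

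Among genes of mitochondrial shape, Mfn2 was the only 1 of 22 fusion and fission genes to pass the test, and adjusted over the list alone 2 passed, Mfn2 and Phb, both lower. This list had a median of 0.02, a mean of -0.02 and a direction that was up in camera (adjusted p = 0.999) and down in fry (0.794). Vapa, which tethers the endoplasmic reticulum to other organelles, rose by 0.64 (SE 0.12, adjusted p = 0.0106; 0.0602 without WT replicate 3). It was the only 1 of 24 genes of mitochondrial motility and ER contacts to pass, and 6 rose adjusted over the list alone. The 24 genes moved upward on balance in fry (adjusted p = 0.0226), but camera, which compares them with all other genes, gave an adjusted p of 0.319.

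Nuclear genes of mitochondrial DNA upkeep and transcription stood higher as a list. Their median log2 fold change was 0.26 over 21 genes (camera adjusted p = 0.0329, and adjusted p = 0.62 with an estimated correlation). Tfam, the protein that packages mitochondrial DNA and starts its transcription (chromosome 10, 71225464 to 71238280), was the only member to pass. It rose by 1.03 (SE 0.18, adjusted p = 0.00739; 0.0561 without WT replicate 3), from 96.4 ± 15.9 to 198 ± 32.7 normalized counts. Adjusted over the list alone, 3 of the 21 rose, with Mterf1a and Mterf3 beside Tfam. The list's own call was lost without WT replicate 2 (adjusted p = 0.0682), KO replicate 1 (0.075) or KO replicate 3 (0.0648), with the trend on GC content and length removed (0.0826) and with a filter of 5 CPM (0.115). Among 29 genes of mitochondrial protein import, Tomm20, a receptor of the outer membrane translocase, rose by 1.51 (SE 0.21, adjusted p = 0.00256), from 61.1 ± 7.14 to 180.5 ± 57.2. No other member passed, adjusted over the list alone Tomm20 rose and Tomm6 and Timm50 fell, and the list gave a camera adjusted p of 0.414.

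Respiratory chain subunits encoded in the nucleus lay slightly lower in KO. The median was -0.16 over 36 complex I genes (camera adjusted p = 0.000435) and -0.13 over 40 genes of complexes II to V (0.00321), and both had an adjusted p = 0.62 with an estimated correlation. In each list 32 members had a fold change below 0, but no single gene passed the test, over all genes or adjusted over the list alone. The closest in complex I were Ndufv1 (-0.39, adjusted p = 0.0715) and Ndufa3 (-0.42, 0.12), and in complexes II to V Atp5k (-0.39, 0.08) and Cox6a1 (-0.33, 0.104). Both calls ended when the trend on GC content and transcript length was removed (adjusted p = 0.0583 and 0.164), and that of complexes II to V also ended without WT replicate 1 (0.059). Genes encoded in mitochondrial DNA were not analysed here.

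Cytosolic ribosomal protein genes also lay lower, with a median of -0.19 over 79 genes and 64 of them below 0 (camera adjusted p = 7.92e-06, and adjusted p = 0.62 with an estimated correlation). With the trend on GC content and transcript length removed, their median was -0.10 (camera adjusted p = 0.0252). Only Rpl35 passed by itself, over all genes and adjusted over the list alone. It fell by 0.47 (SE 0.11, adjusted p = 0.0315; 0.138 without WT replicate 2), and 97.1% of its windows match other genes, so its value is uncertain. Of 31 proteasome genes, Psmb2, a subunit of the core particle, fell by 0.43 (SE 0.10, adjusted p = 0.0248; 0.108 without WT replicate 1), and the list was not called (camera adjusted p = 0.249).

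Genes of the spindle, kinetochore and cohesin fell as a list, with a median of -0.15 over 39 genes (camera adjusted p = 0.00137, and adjusted p = 0.62 with an estimated correlation). Of these, 5 fell and none rose over all genes, and adjusted over the list alone 10 fell and 2 rose. Ckap5, a microtubule polymerase, fell by 0.69 (SE 0.12, adjusted p = 0.0066), from 1082 ± 100 to 669.5 ± 78.4. The kinetochore motor Cenpe fell by 0.60 (SE 0.10, adjusted p = 0.00674), from 3418 ± 45.1 to 2265 ± 252. The cohesin subunit Smc3 fell by 0.57 (SE 0.11, adjusted p = 0.0134; 0.0842 without WT replicate 3) and Cenpf, a kinetochore protein, by 0.57 (SE 0.13, 0.0259; 0.125 without WT replicate 3). The fifth was Tpx2, a spindle assembly factor, at -0.43 (0.0451).

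Maternal-effect genes, whose products stored in the egg are needed by the early embryo, moved in both directions. Over 37 genes the median was -0.20 (camera adjusted p = 0.0364, and adjusted p = 0.62 with an estimated correlation), with 4 falls and 2 rises over all genes and 15 falls and 6 rises adjusted over the list alone. Kdm1b, a histone demethylase needed to set maternal imprints (chromosome 13, 47043499 to 47085279), rose by 1.10 (SE 0.12, adjusted p = 0.00026), from 526 ± 36.4 to 1132 ± 167. Bnc1, a zinc finger protein of germ cells, rose by 0.69 (SE 0.13, adjusted p = 0.00844; 0.0588 without WT replicate 3). Zar1, an RNA-binding protein of the oocyte, fell by 0.55 (SE 0.10, adjusted p = 0.011; 0.0604 without WT replicate 1), from 8010 ± 571 to 5474 ± 472. Khdc3, a member of the subcortical maternal complex, fell by 0.54 (SE 0.11, adjusted p = 0.0145; 0.0747 without WT replicate 1). Khdc3 shares 40% of its windows with the overlapping model Gm20509 and Zar1 41.2% with Gm42668. Nlrp14 (-0.77) and Nlrp5 (-0.80) were the other falls. The list's call was lost without WT replicate 1 (adjusted p = 0.088), WT replicate 3 (0.0866) or KO replicate 1 (0.0644), and with a filter of 5 CPM (0.0958).

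Some other genes of oocyte identity and meiosis changed, in both directions. Over all tested genes, 3.28% were called. Among 41 genes of meiotic arrest and cell cycle, 2 rose and none fell. Wee1, a kinase that inhibits CDK1, rose by 1.34 (SE 0.22, adjusted p = 0.00558), from 59.2 ± 9.16 to 154 ± 44.2. Pde3a, the phosphodiesterase that lowers cyclic AMP in the oocyte, rose by 0.54 (SE 0.13, adjusted p = 0.0304; 0.105 without KO replicate 2). Adjusted over the list alone, 3 rose, with Cdc14b, and Cdc25a, Plk1 and Marf1 fell (camera adjusted p = 0.409). Of 32 genes for oocyte growth factors, the zona pellucida and oocyte transcription factors, Taf4b (1.04), Cd9 (0.68) and Tbpl2 (0.64) rose and none fell, and adjusted over the list alone the same 3 rose and Zp1, Zp2, Zp3 and Fgf8 fell (camera adjusted p = 0.746). Their adjusted p-values were 0.0207, 0.0375 and 0.048, and that of Cd9 was 0.0935 in edgeR. Each lost its call in at least 1 fit without a single library, with adjusted p-values of 0.103 and 0.153 for Taf4b and Cd9 without WT replicate 3 and 0.163 for Tbpl2 without KO replicate 3. Cd9 stood at 1682, 1851 and 3086 in KO replicates 1 to 3, and its lowest log2 fold change in these fits was 0.41. Of 35 genes for maternal mRNA storage and decay, Cnot3 (-0.75, adjusted p = 0.0216) and Pabpn1l (-0.77, 0.0458) fell and Ybx2 (0.53, 0.0382) rose, and adjusted over the list alone 3 rose, with Patl2 and Dcp1a, and 3 fell, with Zcchc6 (camera adjusted p = 0.414). Cnot3 belongs to the CCR4-NOT deadenylase, Pabpn1l is a poly(A)-binding protein of the oocyte and Ybx2 stores maternal mRNA. Cnot3 had an adjusted p of 0.1 without WT replicate 2, and Ybx2 and Pabpn1l had 0.155 and 0.169 without WT replicate 3, and Pabpn1l had an adjusted p of 0.293 in edgeR. Tcstv1 was the only 1 of 16 early embryonic genome activation genes to pass, with a rise of 0.47 (adjusted p = 0.0305; 0.141 without WT replicate 3) and 20.4% of its windows shared with near copies. It was also the only 1 adjusted over the list alone (camera adjusted p = 0.414).

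Stress, death and damage genes showed few changes. Ppp1r15a, which directs dephosphorylation of eIF2α, fell by 0.61 (SE 0.14, adjusted p = 0.0259; 0.142 without WT replicate 3) and was the only 1 of 29 genes of the mitochondrial unfolded protein and integrated stress response to pass, in both adjustments. No gene among 25 of the ER unfolded protein response passed over all genes. The closest were Atf6 (-0.55, adjusted p = 0.0518) and Calr (-0.48, 0.0623), and adjusted over the list alone these and Dnajc3 fell and Derl2 rose. None of 30 apoptosis genes passed in either adjustment, with Casp2 (0.65, 0.132) and Bad (-0.77, 0.216) closest. Brca1 fell by 0.51 (SE 0.12, adjusted p = 0.0371; 0.146 without WT replicate 1) among 23 genes of the p53 and DNA damage response, of which Brca1 and H2afx fell adjusted over the list alone. Map1lc3a, an autophagosome protein, fell by 0.58 (adjusted p = 0.0496) among 35 autophagy and mitophagy genes, and lost its call in every fit without a single library (adjusted p 0.0566 to 0.219). Adjusted over that list alone, Map1lc3a and Tax1bp1 fell and Bcl2l13 rose. None of 33 antioxidant genes passed in either adjustment, with Prdx5 (-0.39, 0.0549) and Txnrd1 (-0.32, 0.18) closest, nor did any of 27 telomere genes, with Atrx at -0.32 (0.126) and Wrap53 at 1.54 (0.186). The camera adjusted p-values of these 7 lists were 0.313, 0.214, 0.961, 0.278, 0.497, 0.176 and 0.94, in the order given here, and the antioxidant list was called lower without WT replicate 2 (adjusted p = 0.0399). The apoptosis list had a median of -0.02 with a mean of 0.01 and the direction up, and the telomere list a median of 0 with a mean of 0.06 and the direction down.

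In lipid and energy metabolism, Ugcg, the glucosylceramide synthase, rose by 0.85 (SE 0.22, adjusted p = 0.0426; 0.162 without WT replicate 3) as the only 1 of 33 sphingolipid genes in both adjustments. No gene passed over all genes among 35 of the tricarboxylic acid cycle and pyruvate use, 19 of glycolysis or 24 of fatty acid oxidation, and adjusted over the lists alone only Hadha of the last did so. The values closest to the threshold were Mdh2 (-0.37, adjusted p = 0.0977) and Idh3g (-0.34, 0.164), Ldhb (-0.59, 0.21) and Aldoa (-0.23, 0.292), and Hadha (-0.58, 0.0514) and Cpt2 (-0.47, 0.113). Ldhb was at 16940 in KO replicate 1 and at 42190 and 40540 in the other KO libraries, and it shares 38% of its windows with Gm5514. Without KO replicate 1 the log2 fold change was -0.16 for Ldhb and -0.27 for Cpt2. The camera adjusted p-values of the sphingolipid, tricarboxylic acid cycle, glycolysis and fatty acid oxidation lists were 0.155, 0.942, 0.249 and 0.249, and that of the cholesterol synthesis list was 0.313.

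**Figure D3:**
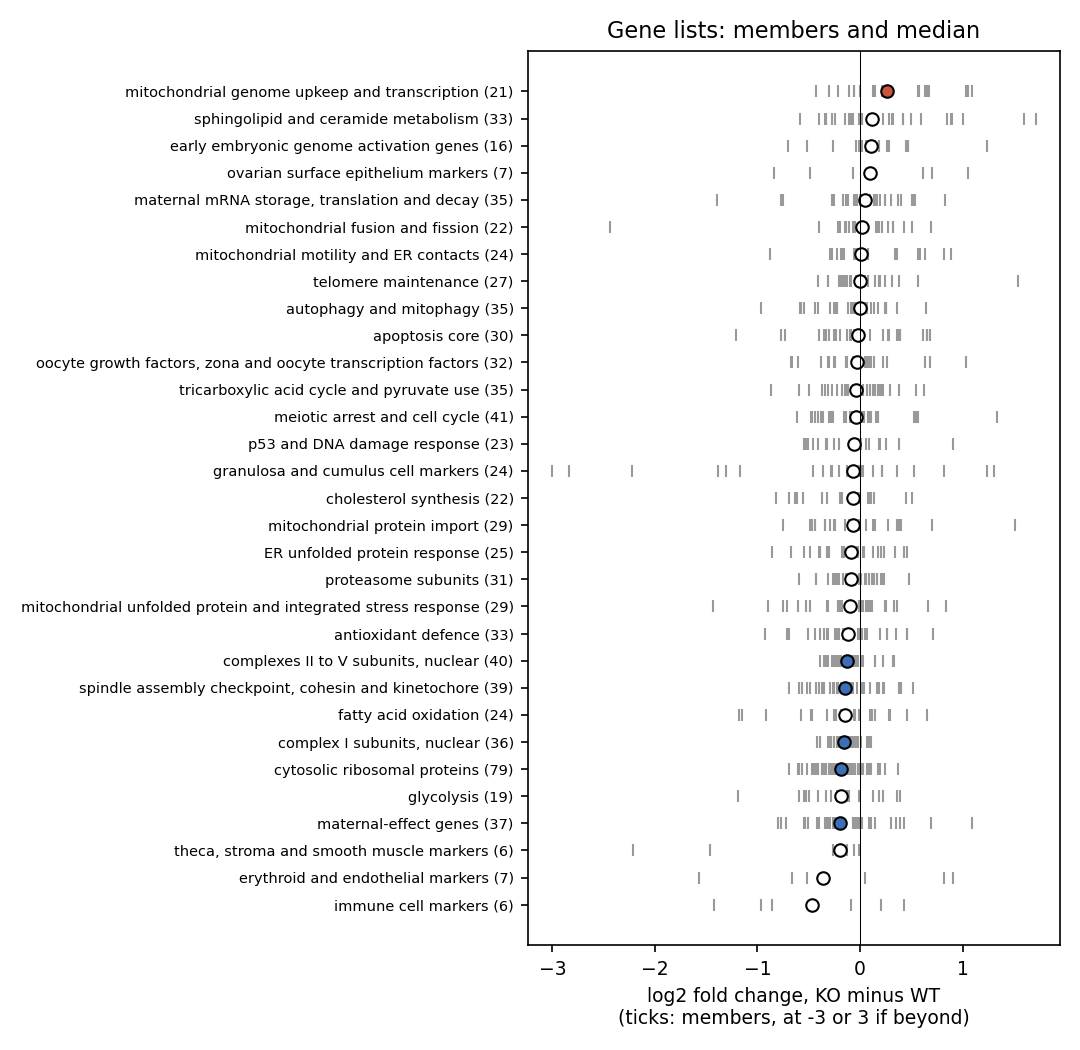
Log2 fold change of KO against WT (x axis) for the members of 31 gene lists, with a tick per member (drawn at -3 or 3 if beyond), a circle for the list's median and the number of tested members in brackets. Filled circles mark the 6 lists called by camera with a preset correlation, 5 with a median below 0 and 1 above.

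Several markers of other ovarian cells were unevenly spread over the WT libraries. Others, such as Serpine2 (2105 to 2967 normalized counts) and Esr2 (1200 to 1315), had similar levels in all 6 libraries. The steroidogenic gene Hsd3b1 had 1270 normalized counts in WT replicate 1, 0.93 in WT replicate 2, 219 in WT replicate 3 and 5.25 to 49.5 in KO. Acta2 of smooth muscle had 78.7 in WT replicate 1, 10.2 in WT replicate 3 and at most 0.899 elsewhere. Lyz2 and Cd74 of immune cells had 24.4 each in WT replicate 1 and 4.62 and 10.2 in WT replicate 3, and were at 0 in WT replicate 2 and all KO libraries. The granulosa marker Inha was not confined to WT. It had 171, 33.5 and 41.6 in WT replicates 1 to 3 and 28.4, 63.4 and 101 in KO replicates 1 to 3. Beside these values, 2 of 24 granulosa and cumulus markers fell, Cyp11a1 and the luteinizing hormone receptor gene Lhcgr, and no marker of that list rose. Lhcgr had 16.6, 2.79 and 10.2 in WT and 1.05, 0 and 0 in KO (log2 fold change -2.84, SE 0.67, adjusted p = 0.0317; 0.141 without WT replicate 1), and its log2 fold change was -3.46 without WT replicate 2. Dcn, a proteoglycan of stromal cells, fell by 2.21 (SE 0.50, adjusted p = 0.0244; 0.114 without WT replicate 1) as the only 1 of 6 theca, stroma and smooth muscle markers. H2-Aa, with 54.3, 96.7 and 67.4 in WT and at most 34.9 in KO, was the only 1 of 6 immune markers to pass. Of 7 erythroid and endothelial markers none passed, with Kdr (-1.57, adjusted p = 0.0885) and Flt1 (-0.66, 0.279) closest, and of 7 surface epithelium markers Lypd6b rose by 0.70 (adjusted p = 0.0261; 0.119 without WT replicate 3). Adjusted over each list alone the counts were the same, except that C1qb among immune markers rose and Kdr fell. With all 6 libraries no list of these was called (camera adjusted p = 0.392, 0.106, 0.414, 0.481 and 0.438). The granulosa and cumulus list was called lower without WT replicate 2 (adjusted p = 0.0399), and the theca, stroma and smooth muscle list without WT replicate 3 (0.0233) or KO replicate 2 (0.0412).

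**Figure D4:**
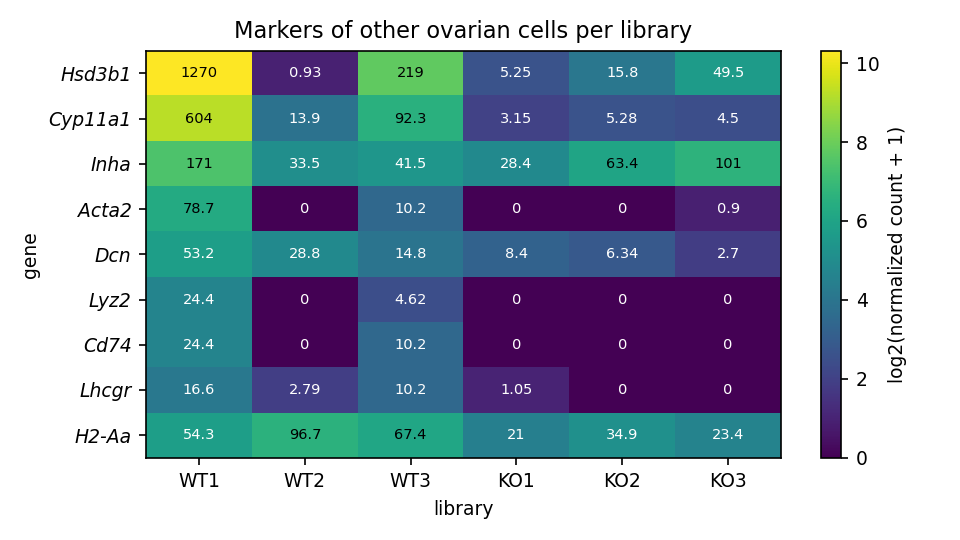
Normalized read count of 9 markers of other ovarian cells (y axis) in the 6 libraries (x axis), printed in each field and coloured by log2(normalized count + 1). The 9 are a selection from the fixed lists, in which other markers, such as Serpine2 and Esr2, had similar counts in all 6 libraries. Hsd3b1 and Cyp11a1 are highest in WT replicate 1, at 1270 and 604, and H2-Aa is higher in all 3 WT libraries than in any KO library.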

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

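Chosen after seeing the data were the edgeR fit with TMM, the limma fits with TMM scaling, a 5 CPM filter or a replicate block, the removal of the GC and length trend, and leaving out a library with the genes of the 6-library filter. Mfn2 was lower in KO under every alternative that gave it an adjusted p, and Mfn1 passed the test under none. Against 351 rises and 264 falls, the rises came to 561 in edgeR with upper-quartile factors, 579 in edgeR with no filter and 531 in edgeR with a filter of 5 CPM, and the falls to 401 in DESeq2. The cause was not tested. By construction, an adjusted p under 0.10 gave 681 and 548 and a 2-fold minimum 124 and 59. Leaving out 1 library, with fewer samples, gave 39 to 459 rises and 30 to 430 falls. The lowest rises came without KO replicate 3 with the genes of the 6-library filter (39 and 32), where the filter applied to the 5 libraries gave 194 and 185. Of the genes called, 607 kept their call in limma with TMM scaling, 434 with a pseudocount of 0.1, 460 with the GC and length trend removed and 403 with a replicate block, none with the opposite sign. Of the 51 named genes called, 1, 10, 6 and 9 lost the call in these fits, in that order.

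Gene list calls depended on the test. Against 6 lists called, camera with an estimated correlation called 0, and fry kept 0 of the 6 and called 1 other. With the GC and length trend removed 3 of the 6 were kept. Without a single library between 4 and 7 lists were called, of which 4 to 6 were among the 6. The cause was not tested. No list or named gene that was called under either setting changed direction.

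The replicate numbers showed no sign of pairing the samples: same-numbered KO and WT libraries deviated from their group means with r = -0.17, -0.08 and -0.04 across genes. So few values cannot exclude a shared litter, day or batch. No sample correlated best with its own number. With the replicate block in limma there were 246 rises and 175 falls, in edgeR 363 and 261, and camera called 5 lists, without the maternal-effect list (adjusted p = 0.0528). Depth limits low genes: Mfn2 rests on 5 reads in each KO library.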

Other observations

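The gene families, the per-library values of this part and the tests on RNA of other cells, on the GC trend between libraries and on the GC and length trend in single lists were chosen after the data were seen. Genes were grouped into 169 families by the stem of their symbol, each with at least 10 tested members. The Nlrp family, to which Nlrp5 of the subcortical maternal complex belongs, lay lower in KO with a median log2 fold change of -0.33 over 14 genes, 13 of them below 0 (camera adjusted p = 0.000171, and adjusted p = 0.931 with an estimated correlation). Nlrp14 (-0.77), Nlrp5 (-0.80) and Nlrp9b (-0.44) fell and none rose, and Nlrp2, Nlrp4f, Nlrp5 and Nlrp14 are also in the maternal-effect list. Without each library in turn the family's adjusted p ran from 1.02e-05 to 0.0272, and it was 1.3e-07 with the GC and length trend removed. The Fbxw family of F-box genes had a median of -0.24 over 24 genes (camera adjusted p = 0.0113, and adjusted p = 0.931 with an estimated correlation). Fbxw14, Fbxw16, Fbxw18, Fbxw21 and Fbxw24 fell and Fbxw11, at a far lower level, rose by 1.12. The copies share sequence to unlike degrees. Windows matching other genes made up 81.2% in Fbxw14, 26.1% in Fbxw16, 5.2% in Fbxw18, 6.9% in Fbxw21 and 7% in Fbxw24. Without WT replicate 1 the camera adjusted p of the Fbxw family was 0.0577. In all, 7 families were called and none with an estimated correlation. The others were Ube (adjusted p = 0.0113) and Zfp (0.0474), higher, and Rpl (0.012), Cox (0.016) and Hist (0.016), lower, and these 5 calls ended with the GC and length trend removed (adjusted p = 0.199, 0.581, 0.388, 0.388 and 0.452), without WT replicate 1 (0.0577, 0.0577, 0.105, 0.0773 and 0.0664) and without WT replicate 2 (0.0771, 0.0972, 0.125, 0.114 and 0.0972). Without KO replicate 3 the calls of Zfp (0.215), Rpl (0.206), Cox (0.179) and Hist (0.171) ended, as did that of Zfp without WT replicate 3 (0.0703) and that of Ube without KO replicate 1 (0.0695).

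Mt2, the neighbour of Mt1, did not pass the test and had the opposite sign, a difference that was not tested itself. It had 34.4, 3.72 and 12 normalized counts in WT and 3.15, 2.11 and 0.899 in KO (log2 fold change -2.16, adjusted p = 0.0835), beside the rise of Mt1 by 4.98, and it shares 33.3% of its windows with Gm45774. KO replicate 1 was low in several abundant oocyte transcripts, with Zp3 at 12400 against 22300 and 29700 in the other KO libraries, Nlrp14 at 21700 against 32800 and 36600, and Padi6 at 5460 against 14800 and 14900.

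The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Each split other than the real one mixes the genotypes unevenly, so a genotype difference stays partly between its groups and widens the spread within them. Its gene and list calls therefore cannot tell genotype from another structure of the libraries. The real split called 615 genes and the highest of the other splits 0, so that 1 of the 10 splits gave as many. For gene lists the real split called 6 and another split 7, so that 2 of the 10 gave as many, and the cytosolic ribosomal protein list was called in 4 of the 9 other splits, the lists of complex I, complexes II to V and the spindle in 2 each, that of maternal-effect genes in 1 and that of mitochondrial genome upkeep in 0.

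Ribosomal protein and respiratory chain genes lay lower in KO, and KO replicate 1 alone is argued against, since without it the median log2 fold change of the 155 members was -0.19, against -0.16 with it, and all 3 lists stayed called. A trend on GC content and length was first tested on the 3 lists jointly (median -0.16 to -0.11, 1 of 3 lists still called) and split into parts after that was seen. It stays open for the ribosomal proteins, whose median went from -0.19 (SE 0.02) to -0.10 (SE 0.02) with the trend removed and, relative to that of all genes, from -0.18 to -0.08, although the call that stayed (adjusted p = 0.0252) counts against it as the whole cause. It stays open too for the respiratory lists, whose median went from -0.15 (SE 0.02) to -0.12 (SE 0.02), or from -0.14 to -0.10 relative to all genes, and whose calls ended (adjusted p = 0.0583 and 0.164) because the mean z of their members came closer to that of the other genes, from -1.19 to -0.754 and from -0.962 to -0.503, while its error went from 0.283 to 0.282 and stayed at 0.272. The SE beside each of these medians is that of the members' mean. It treats the genes as independent and holds no spread between libraries. A difference due to genotype was not tested separately. A structure of the libraries stays open too, since the calls in other splits cannot tell it from genotype.

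Cyp11a1, Lhcgr and Dcn were lower in KO. RNA of other ovarian cells in WT replicate 1 is a candidate source of their WT level. The other fixed markers of granulosa, stromal, immune, endothelial and epithelial cells with at least 3 reads in any library, a filter other than that of the tests, numbered 63. Of these, 34 (54%) were highest in that library, where 16.7% would be by chance if markers of the same cells were independent, which they are not. They were 13 of 24 granulosa, 9 of 12 stromal, 6 of 12 immune, 4 of 8 endothelial and 2 of 7 epithelial markers, with Hsd3b1 at 1270 and Inha at 171. Some, such as Col1a2 and Tyrobp, had reads in WT replicate 1 only and so passed the filter through it alone. Of the 63, 20 had at least 10 normalized counts in all 6 libraries. Without WT replicate 1 the median log2 fold change of the 3 genes was -2.36, against -2.84 with it, so RNA in the other WT libraries or an effect of genotype may account for the rest. For H2-Aa the same source is argued against, because its log2 fold change without WT replicate 1 was -1.61 (SE 0.32).

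Genes that rose had a lower GC content (median 45.4%) than genes that fell (48.7%), a difference of 3.28 percentage points that turned to -1.49 with the GC and length trend removed, a correction that itself acts on the GC content of the genes called. A hypothesis written before its test was that rising genes carry a cytoplasmic polyadenylation element near their 3′ end, since Smart-Seq2 primes on poly(A) tails. Among genes with an annotated 3′ UTR the element lay in the last 150 bases of 31.8% of rising (299) and 28.9% of falling (187) genes. The odds ratio at fixed GC content of the same bases was 0.899 (95% interval 0.583 to 1.39 in a logistic model). This interval allows the element to be either rarer or more frequent in rising genes, so the test cannot decide the hypothesis, which stays open. A GC trend between libraries stays open: genes that were not called had a Spearman rho of -0.20 between fold change and GC content, across 9417 genes that are not independent replicates. The libraries' own rho was 0.22, 0.23 and -0.01 in WT and -0.21, -0.17 and 0.01 in KO, and the largest range within a group was 0.884 of the difference between groups, so this trend and genotype cannot be told apart.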
